A study of Arabidopsis thaliana with 8 samples.

How the data were processed

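Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Arabidopsis thaliana seedlings 7 days after germination. GFP-tagged proteins were pulled down with a GFP-binding resin. In one line the protein was AtGBPL3 (a guanylate-binding protein-like GTPase) tagged with GFP, expressed from its own promoter in the gbpl3-5 mutant. In the other line the protein was the histone H2B tagged with GFP, expressed from the 35S promoter of cauliflower mosaic virus. The 8 samples form 4 groups, a pulldown and an input of each fusion, with 2 replicates in each. A peak list was used here for each of the 4 pulldown samples. The inputs were not analysed here. The labels do not say whether the replicates came from separate cultures of seedlings, so overlaps between replicates may measure only technical spread. The p-values describe where called regions lie and measure no spread between replicates.

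Per the submitters' processing notes, BWA 0.7.12, MACS2 2.1.0 and the genome build TAIR10 were used; their options, and whether an input served as the control for peak calling, are not given in the sources used here. Each deposited list belongs to a single sample, so the authors' peaks were called per sample and replicates could be compared by overlap. The deposited lists have the columns of a MACS2 narrow peak file without a header. Per the deposited values, the fold enrichment of a peak (a linear ratio of the summit over its local background) stands in column 7. The −log10 p and −log10 q of the deposited peaks stand in columns 8 and 9, and the authors' score in column 5 equals 10 times the −log10 q, cut to a whole number. The offset of the summit in column 10 of the deposited lists was used to place summits. These values describe a peak within its own list, and folds of different lists were not tested against each other. The lowest −log10 q in the lists lay between 1.30 and 1.39. Read counts and sequencing depths were not used here, so the depth behind each fold is unknown, and the number of peaks per list can move with it.

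Lines of a list with the same start and end are several summits of 1 interval; they were joined into 1 peak with its highest fold, its highest −log10 q and the summit of the highest −log10 q. Peaks on the mitochondrial and plastid chromosomes were left out of the tests. Regions called in both replicates were runs of overlapping peaks (at least 1 bp) that held a peak of each replicate; the fold of a region was the mean of the highest fold in each replicate. Regions with neighbours within 50 kb were joined into loci for description. Pericentromeres were taken as 3 Mb to either side of an approximate centromere midpoint written before the data were examined (15.1, 3.6, 13.7, 4.0 and 11.7 Mb on chromosomes 1 to 5), together 25.2% of the 119 Mb of nuclear genome. Chromosome lengths were taken as the last position that a gene or a peak reached.

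No genome sequence was used here. Gene names and positions came from a RefSeq gene table of the assembly TAIR10.1, whose 37887 nuclear genes were placed against the peaks and from which no coordinates are given. The builds are not named alike, so the fit was checked: 91.2 to 93.5% of the H2B replicate 2 peaks had their summit in a protein-coding gene on each chromosome, and after the peaks were moved by 5 to 50 kb (20 shifts) this was 58.4 to 69.1%. All coordinates given are those of the authors' peaks, counted from 1. The table holds neither strand nor exons. Exon, intron and untranslated classes, and a class upstream of genes, were planned but could not be formed. Summits were put into 5 classes instead (protein-coding gene, non-coding RNA gene, pseudogene, within 1 kb of a gene on either side, intergenic). The planned class of transposable elements or pseudogenes was formed from pseudogenes alone, so an intergenic summit may still lie in a transposable element. Of the 15 gene lists, fixed at the same time as the midpoints, 7 were written as identifiers, all 75 of which were found, and 8 were patterns on gene type, symbol or synonym, which take in only genes so named.

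Overlaps, pericentromeric shares, classes and gene lists were tested by permutation of the region positions: 10000 random placements of the regions with the same width on the same chromosome. The smallest p these can give is 0.0001. Overlaps and shares were tested on the side of the difference; classes and gene lists were tested on both sides with Benjamini-Hochberg adjustment within each fusion, over 5 classes or 15 lists. The fusions were compared by Fisher's exact test (2-sided) with the conditional odds ratio and its exact 95% interval. Shares carry Wilson 95% intervals, which cover counting error only. Regions are not replicates: neighbouring regions are not independent, and each p describes where the called regions lie in these libraries. With 2 libraries against 2, an exact permutation test of the libraries cannot give a 2-sided p under 0.333, and no model of the values per library was fitted.

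The rule for named regions took the 25 regions with the highest mean fold of each fusion, for GBPL3 also the 5 highest without an H2B peak, and at most 4 genes of each list. A list gene counted as hit with a region in its body or within 1 kb, so the peak of 1 of the replicates in that region can lie farther off. Alternatives were a reciprocal overlap of 50%, summits within 200 bp, −log10 q of at least 5, organelle peaks kept, random placement within the same compartment (pericentromere or arm), pericentromeres of 2 and 4 Mb, each replicate left out, classes by any overlap, gene bodies alone or with 2 kb, peaks of either replicate, and strata by replicate number.

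The code was tested on simulated region sets on the same chromosomes, with 500 placements each. Of 200 sets of 64 regions placed at random for the GBPL3 pericentromeric share, 5.50% were called at a 2-sided 0.05, and all 200 sets with about 50% of the regions planted in pericentromeres were called. For the GBPL3 overlap with H2B, 3.00% of 200 random sets of 64 regions were called, and 99.5% of those with about 25% planted on H2B peaks. The random sets were placed independently, as the test itself assumes, so they check the code and not the clustered regions of these data. The shares and overlaps of the real regions were tested 1-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.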

Results

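GBPL3-GFP and H2B-GFP were pulled down from 7-day-old Arabidopsis seedlings with the same GFP-binding resin, and the genomic DNA that came with them was read out as peak lists, 2 replicates for each fusion. AtGBPL3 is a large GTPase of the guanylate-binding family, and H2B is a core histone found along the whole chromatin. On the nuclear chromosomes, the GBPL3 lists held 87 and 81 peaks covering 44.0 and 45.0 kb in replicates 1 and 2. The H2B lists held 1361 and 8608 peaks covering 575 and 4547 kb. The authors' fold enrichment over the local background, a value of each peak within its list, had a median of 5.71 (SD 2.78 over 87 peaks) and 4.21 (SD 5.19 over 81 peaks) in the GBPL3 lists, with highest values of 14.2 and 43.8. In the H2B lists the median was 1.88 (SD 0.227) and 1.76 (SD 0.216), with highest values of 3.86 and 3.6. Depth is unknown for all 4 libraries.

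The first question was whether the replicates of a fusion found the same places. Of the GBPL3 peaks, 66 of 87 in replicate 1 (75.9%, 95% interval 65.9 to 83.6) overlapped a replicate 2 peak and 66 of 81 in replicate 2 (81.5%, 71.7 to 88.4) overlapped a replicate 1 peak. They formed 64 regions called in both, with a median width of 386.5 bp and 40.6 kb in all. In 62 of the 64 the fold was higher in replicate 1, with a median ratio of replicate 2 over replicate 1 of 0.662. The Spearman correlation of the folds between replicates was 0.936, and the Pearson correlation of the log2 folds was 0.749. The peaks of a single replicate were 21 in replicate 1, of which 19 lay in pericentromeres, and 15 in replicate 2, of which 6 did. Of those in replicate 2, 3 lay in CRWN4 (AT5G65770), which encodes a lamin-like protein of the nuclear periphery and is overlapped by AT5G65780 in the gene table. The strongest of them, on chromosome 5 (26314310 to 26315646), had a fold of 23.3, ranking 2 of 81 in its list, and the 3 peaks covered 55.1% of the gene. Replicate 1 had no peak in the gene, which is named here after its values were seen.

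H2B peaks were shared less evenly, since the lists differed 6.32 times in length. Of the replicate 1 peaks, 848 of 1361 (62.3%, 59.7 to 64.8) overlapped a replicate 2 peak, and of the replicate 2 peaks 827 of 8608 (9.61%, 9.0 to 10.2) overlapped a replicate 1 peak. The 815 regions called in both covered 750 kb with a median width of 822 bp. Their folds correlated weakly between replicates (Spearman 0.173, Pearson of log2 folds 0.280). Random placement gave 0.0821% for GBPL3 replicate 1 and 6.77% for H2B replicate 1, and the share was above this in both fusions and both directions (permutation p = 0.0001 each, the smallest that 10000 placements can give, 1-sided). With reciprocal overlap of 50% the H2B share was 26.8%, and with the 1361 strongest replicate 2 peaks by q it was 29.6% (random placement 1.37%).

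Where on the chromosomes the fusions sat was the next question, since the series concerns silencing at the nuclear periphery and silent chromatin of this plant is concentrated around centromeres. GBPL3 regions gathered around the centromeres: 52 of 64 (81.3%, 70.0 to 88.9) lay within 3 Mb of a centromere midpoint, against 27.5% after random placement (permutation p = 0.0001, the smallest possible, 1-sided). As many as 40 lay within 200 kb of a midpoint, where H2B had 1 of its 815 regions. H2B regions lay in the arms, with 58 of 815 (7.12%, 5.55 to 9.09) in pericentromeres against 25.1% after random placement (permutation p = 0.0001, the smallest possible, 1-sided). The odds of lying in a pericentromere were 55.9 times higher for GBPL3 than for H2B regions (95% interval 27.6 to 122, Fisher's exact p = 3.57e-41), and 34.7 times with GBPL3 replicate 2 alone.

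**Figure D1:**
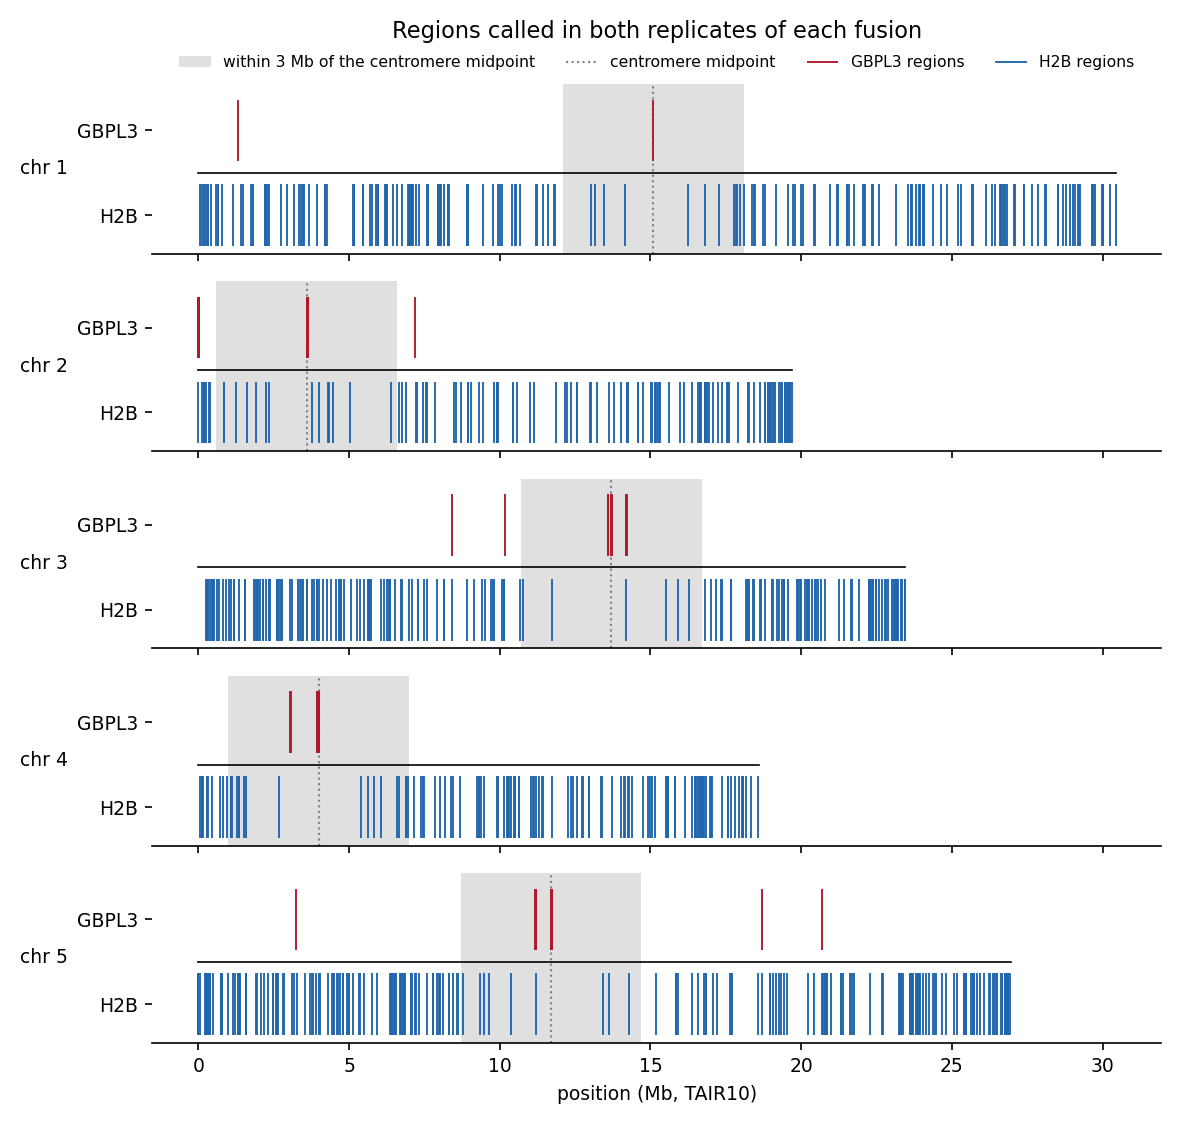
Positions (Mb, TAIR10) of the 64 GBPL3 regions (red) and the 815 H2B regions (blue) called in both replicates on chromosomes 1 to 5, with 3 Mb to either side of each centromere midpoint (dotted) shaded. Of the GBPL3 regions 52 fall in the shaded parts, many so close together that their lines merge, and of the H2B regions 58 do.

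The shares of the single libraries lay apart by fusion: 82.8% (73.5 to 89.3) and 72.8% (62.3 to 81.3) of the GBPL3 peaks and 8.08% (6.75 to 9.65) and 6.89% (6.37 to 7.44) of the H2B peaks were pericentromeric in replicates 1 and 2. GBPL3 regions came in clusters, which makes the p-values too small: joined across gaps of up to 50 kb they formed 17 loci, of which 9 were pericentromeric (52.9%, random placement 25.5%, 1-sided permutation p = 0.0131), a comparison chosen after the regions were seen. At the level of loci the odds ratio between the fusions was 9.95.

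**Figure D2:**
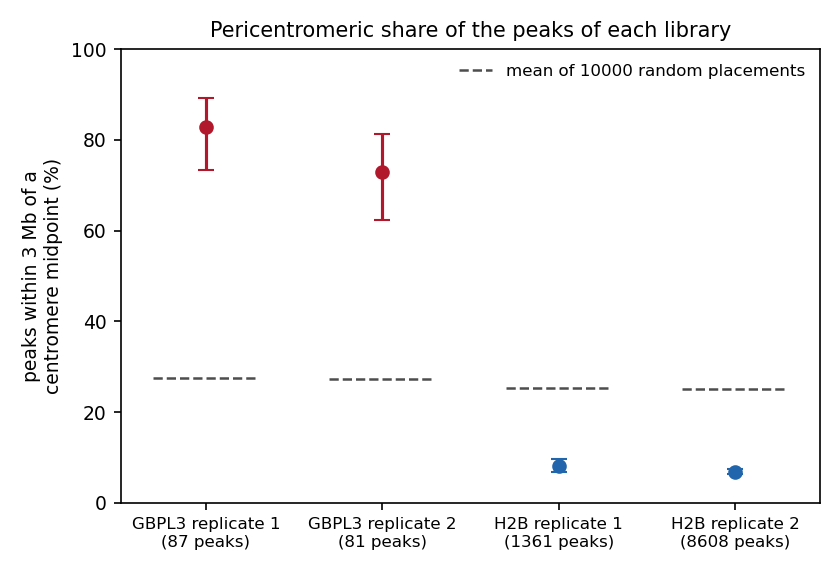
Percent of the nuclear peaks of each library that lie within 3 Mb of a centromere midpoint (points) with Wilson 95% intervals (bars), and the mean of 10000 random placements (dashed lines). Both GBPL3 libraries (82.8 and 72.8%) lie above the dashed lines and both H2B libraries (8.08 and 6.89%) below.

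The largest GBPL3 clusters lay next to the centromere midpoints. Chromosome 4 held 14 regions between 3950499 and 4010356, with folds of up to 9.88 and 6.11 in replicates 1 and 2. Most were intergenic with no gene within 1 kb, and the others lay at or within 1 kb of the pseudogenes AT4G06700 and AT4G06708. Chromosome 2 held 11 regions between 3607026 and 3626484, of which several lay within the protein-coding genes AT2G07981 and AT2G08986; the strongest of these, in AT2G08986 (3622454 to 3622781), had folds of 9.61 and 6.27. On chromosome 5, 10 intergenic regions lay between 11708120 and 11736274, the strongest with folds of 7.89 and 4.95. Chromosome 3 had 2 regions between 13705800 and 13709954 (folds of up to 7.29 and 5.05) and 2 between 13589169 and 13592496 (8.54 and 5.44), none of them within 1 kb of a gene. Farther out, 3 regions on chromosome 5 (11184714 to 11187507) near the pseudogene AT5G29550 reached folds of 14.2 and 9.31, and 2 on chromosome 4 (3054346 to 3061205), of which 1 lay in the pseudogene AT4G06477, reached 10.3 and 9.02. On chromosome 1 a single region in AT1G40104 (15083536 to 15083844) had folds of 3.17 and 2.27.

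GBPL3 regions also lay at the genes for ribosomal RNA. All 4 nuclear rRNA genes of the table were hit by a GBPL3 region (0.0111 hit on average after random placement, adjusted permutation p = 0.003 over 15 lists). AT3G41768 and AT3G41979 lay in a cluster of 7 regions on chromosome 3 (14190523 to 14223335), with folds of 12.6 and 8.05 at AT3G41768 (14197914 to 14198429) and 12.8 and 8.29 beside AT3G41979 (14200804 to 14204095) in replicates 1 and 2. AT2G01010 and AT2G01020 lay in a cluster of 5 regions at the start of chromosome 2 (1122 to 10362), with folds of 10.0 and 6.50 at AT2G01010 (3226 to 3813) and 8.67 and 5.12 at AT2G01020 (5454 to 6109). In total 11 regions lay within 10 kb of a nuclear rRNA gene. The 4 genes stand in 2 clusters and are repeated in the genome, so their hits are not independent.

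Only 7 GBPL3 regions lay neither in a pericentromere nor near an rRNA gene. The strongest spanned the space between AT5G46060 and AT5G46070 on chromosome 5 (18682475 to 18683933) and reached into both genes. AT5G46070 is 1 of the 3 guanylate-binding family genes in the lists (1 of 3 hit, adjusted permutation p = 0.1785, so the list did not pass). Its fold was 43.8 in replicate 2, the highest of that list, and 7.13 in replicate 1, ranking 30 of 87. Another lay at AT1G04680 on chromosome 1 (1307720 to 1309068), with folds of 9.12 and 14.4. The rest had 1 region each in AT3G23460 (chromosome 3, 8413943 to 8414294, folds of 10.1 and 4.32), AT2G16586 (chromosome 2, 7190916 to 7191305, 6.50 and 4.05), AT3G27510 (chromosome 3, 10187981 to 10188340, 5.94 and 4.43), AT5G50820, the NAC-family gene NAC097 (chromosome 5, 20679965 to 20680216, 5.61 and 3.77) and AT5G10340 (chromosome 5, 3253098 to 3253320, 4.64 and 2.62). The other 13 lists had no gene with a GBPL3 region of both replicates and an adjusted p of 1: photosynthesis (0 of 20), nuclear envelope (0 of 11), Polycomb targets (0 of 18), salicylic acid and immunity (0 of 13), heat shock (0 of 5), histone H2B (0 of 5), tRNA genes (0 of 625), small nuclear and nucleolar RNA (0 of 369), transposable elements (0 of 17), ribosomal proteins (0 of 76), NLR-type resistance (0 of 7), F-box (0 of 31) and defensin-like genes (0 of 89). Random placement gave fewer than 1 hit on average for each of these lists, so a lack of GBPL3 there was not detectable with 64 regions.

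Whether GBPL3 sites were also sites of a general chromatin protein with the same tag was asked by overlap with the H2B peaks. Of the 64 GBPL3 regions, 15 (23.4%, 14.7 to 35.1) overlapped an H2B peak of either replicate, against 8.33% after random placement (1-sided permutation p = 0.0003). With a reciprocal overlap of 50% only 5 did (7.81%, random placement 1.80%, 1-sided permutation p = 0.0049). The rRNA clusters held 9 of the 15: 9 of 11 regions near rRNA genes overlapped an H2B peak, and 6 of the 53 others did (11.3%, 5.29 to 22.6; random placement 7.78%, 1-sided permutation p = 0.2276). H2B peaks are scarce in pericentromeres, and with placement kept to the same compartment random overlap was 3.90% for the 64 regions (1-sided permutation p = 0.0001, the smallest possible) and 3.37% for the 53, where the 11.3% then passed (1-sided permutation p = 0.0081). These 6 were AT5G46070, where H2B folds were 1.74 and 1.69, 2 of the 3 regions near AT5G29550 on chromosome 5, both between 3054346 and 3061205 on chromosome 4, and 1 on chromosome 3 (13589877 to 13592496). Of the 40 regions within 200 kb of a centromere midpoint 1 overlapped an H2B peak. The 5 strongest regions without an H2B peak were AT1G04680, an intergenic one on chromosome 5 (11187263 to 11187507, folds of 8.39 and 8.10), an intergenic one on chromosome 4 (3953382 to 3953772, 9.88 and 6.11), and 2 in AT2G08986 on chromosome 2 (3622454 to 3622781, and 3625847 to 3626484 with 8.92 and 5.74). All 15 overlaps were with replicate 1 of H2B, the shorter list; with H2B replicate 2 alone the overlap was 4 of 64 (6.25%, random placement 7.91%, 1-sided permutation p = 0.4182, and 3.67% within the compartment, p = 0.2069). Splitting the regions by rRNA genes was chosen after they were seen.

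The genes beneath the fusions differed as their positions did. GBPL3 summits were intergenic in 31 of 64 regions (48.4%, random placement 10.9%, adjusted permutation p = 0.001) and in non-coding RNA genes in 5 (7.81%, random placement 1.35%, adjusted permutation p = 0.0067). All 5 of the latter lay within 10 kb of an rRNA gene, and 0 of the 53 other regions had a summit in a non-coding RNA gene (adjusted permutation p = 0.974). They were in protein-coding genes in 19 (29.7%, random placement 53.1%, adjusted permutation p = 0.001), in a pseudogene in 1 (1.56%, and 2.47% in replicate 2 alone, random placement 9.45%, adjusted permutation p = 0.0262) and within 1 kb of a gene in 8 (12.5%, random placement 25.2%, adjusted permutation p = 0.0213). Without the regions near rRNA genes the pseudogene share was 1.89% and no longer passed (adjusted permutation p = 0.0948). The share within 1 kb of a gene did not pass in replicate 1 alone (17.2%, adjusted permutation p = 0.1028) or by any overlap (31.3%, adjusted permutation p = 0.0824). Classes were not counted once per locus. Clusters such as those on chromosome 4 (14 regions) and chromosome 5 (10 regions), both mostly intergenic, make the GBPL3 class p-values too small. H2B summits lay in protein-coding genes in 664 of 815 regions (81.5%, random placement 54.2%, adjusted permutation p = 0.0002). They were fewer than after random placement in pseudogenes (33, 4.05% against 8.67%), within 1 kb of genes (83, 10.2% against 24.9%) and in intergenic space (29, 3.56% against 11.0%), each with an adjusted permutation p = 0.0002. In replicate 2 alone these shares were lower, 1.45, 3.90 and 1.17%. In non-coding RNA genes H2B had 6 (0.736% against 1.34%, adjusted permutation p = 0.1586), and 0.743% in replicate 2 alone, which passed (adjusted permutation p = 0.0002). With placement kept to the same compartment, random regions gave 29.8% in protein-coding genes for GBPL3 (adjusted permutation p = 1) and 3.98% in pseudogenes for H2B (adjusted permutation p = 0.9774). The GBPL3 intergenic share stayed above the 17.1% of such placements. Its shares in pseudogenes and within 1 kb of a gene stayed below their 23.6 and 28.3% (adjusted permutation p = 0.0005 and 0.007). Among the 43 H2B regions with a −log10 q of at least 5 in both replicates, the directions turned: 34.9% lay in protein-coding genes, 16.3% in pseudogenes and 20.9% in intergenic space, against 54.8, 8.35 and 11.0% after random placement (adjusted permutation p = 0.072, 0.1648 and 0.1347).

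**Figure D3:**
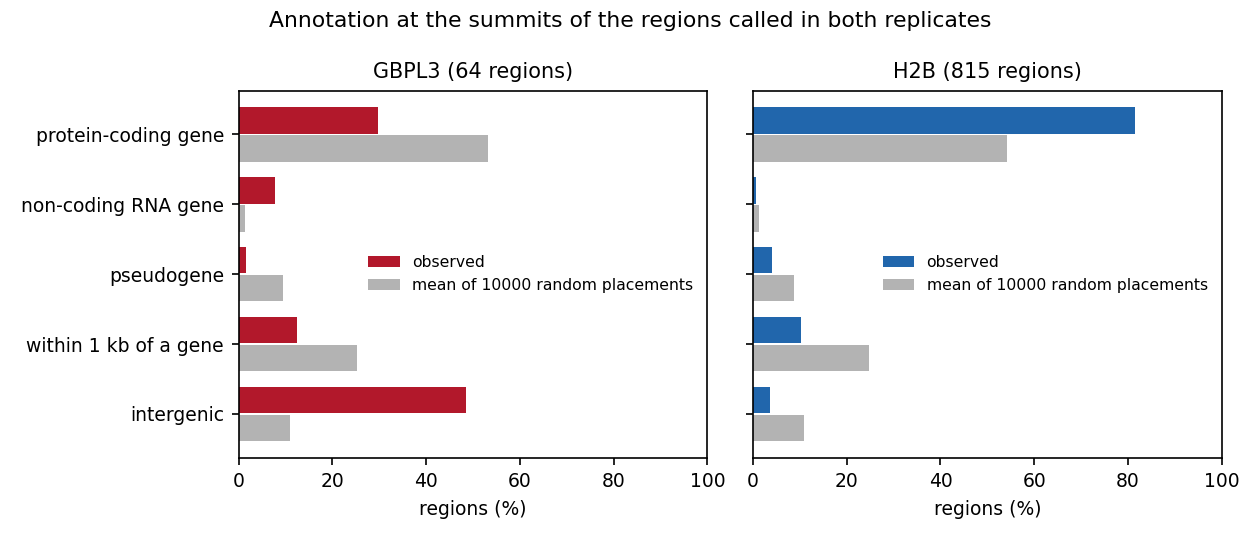
Percent of the regions called in both replicates with their summit in each annotation class (coloured bars), for 64 GBPL3 and 815 H2B regions, beside the mean of 10000 random placements (grey bars). Intergenic summits make up 48.4% of the GBPL3 and 3.56% of the H2B regions, and summits in protein-coding genes 29.7% and 81.5%.

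Set against H2B, GBPL3 regions had higher odds of an intergenic summit (odds ratio 25.2, exact 95% interval 13.1 to 49.1, adjusted p = 2.51e-22) and of a summit in a non-coding RNA gene (11.4, 2.66 to 46.1, adjusted p = 9.6e-04), the latter resting on the rRNA clusters (0 without them, adjusted p = 1). Odds of a summit in a protein-coding gene were lower (0.0964, exact interval 0.0517 to 0.174, adjusted p = 3.17e-17). Pseudogenes (0.376, 0.00910 to 2.33) and the space within 1 kb of genes (1.26, 0.501 to 2.78) did not pass, each with an adjusted p = 0.524 in Fisher's exact tests. Since the GBPL3 regions came in clusters, the p-values of the classes that passed are too small.

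The strongest H2B regions lay in the arms, 22 of the 25 with the highest fold, as did most H2B regions. The order of H2B regions by fold was only weakly shared between replicates (Spearman 0.173). Of all 815 regions 7.12% were pericentromeric, and of the 64 with the highest fold 12.5%. The highest stood near AT1G68490 on chromosome 1 (25696672 to 25698404) with folds of 3.86 and 3.6 in replicates 1 and 2. It was followed by a region near EMB2820 (AT5G24670, chromosome 5, 8446157 to 8447051, 2.69 and 3.32) and by an intergenic one on chromosome 1 (7985456 to 7986054, 3.12 and 2.65). Pseudogenes were under several, among them AT5G38037 (chromosome 5, 15183457 to 15184474, 2.66 and 3.04), AT3G10100 (chromosome 3, 3111181 to 3115490, 2.53 and 2.99) and AT4G20730 (chromosome 4, 11117832 to 11120734, 2.88 and 2.34). Protein-coding genes at the rest included AGP6, an arabinogalactan protein gene (AT5G14380, chromosome 5, 4636005 to 4636568, 2.75 and 2.63), and the transcription factor gene ERF7 (AT3G20310, chromosome 3, 7085895 to 7086779, 2.54 and 2.62). COL3, a relative of the flowering gene CONSTANS (AT2G24790, chromosome 2, 10565396 to 10567317, 2.48 and 2.68), and RAP2.1, an AP2-type factor gene with the region within 1 kb (AT1G46768, chromosome 1, 17267099 to 17268387, 2.09 and 3.27), were also among them. Regions also lay at chromosome ends, at the start of chromosome 5 (112 to 407, 2.75 and 2.40) and at the end of chromosome 2 (19697087 to 19697774, 2.91 and 2.22).

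No gene list passed for the H2B regions of both replicates (15 lists). Transposable elements had 3 of 17 genes hit (adjusted permutation p = 0.369, unadjusted 2-sided permutation p = 0.0246, the only list under 0.05 before adjustment), and by gene bodies alone the same count passed (adjusted permutation p = 0.048). These were all Sadhu retroelements, SADHU6-1 (folds of 2.25 and 1.85), SADHU8-1 (2.23 and 1.81) and SADHU1-1 (1.83 and 2.13). The list was formed by pattern and takes in only genes so named, so it does not stand for transposable elements at large. Photosynthesis had 1 of 20, the antenna gene LHCB6 (1.90 and 1.63), and the nuclear envelope 1 of 11, WIP1 (1.64 and 1.56), each with an adjusted p of 1. Salicylic acid and immunity had 1 of 13 (adjusted p of 1), ICS1 of salicylic acid synthesis, with a replicate 2 peak within 1 kb (2.03) and the replicate 1 peak of the same region farther off, in QKY. There were 11 of 625 tRNA genes, the highest AT1G76000 (2.34 and 2.25). The hits held 2 of 76 ribosomal proteins (RPL4 with 1.70 and 2.26 within 1 kb, MRPL11 with 1.77 and 1.46) and 2 of 31 F-box genes (KUF1 with 1.61 and 2.15, AT1G80440 with 1.66 and 1.65), and these 3 lists again had an adjusted p of 1. The list of rRNA genes had 1 of 4, AT2G01010 (1.55 and 1.29, adjusted permutation p = 0.67), the guanylate-binding family 1 of 3, AT5G46070 (1.74 and 1.69, adjusted permutation p = 0.9114), and small nuclear and nucleolar RNA 1 of 369, AT1G05137 (1.75 and 2.05, adjusted permutation p = 0.498). Polycomb targets (0 of 18), heat shock (0 of 5), histone H2B (0 of 5), NLR-type resistance (0 of 7) and defensin-like genes (0 of 89) were without a region of both replicates, with an adjusted p of 0.9114 for the defensin-like genes and of 1 for the others. With peaks of either replicate, most of them from replicate 2, photosynthesis rose to 13 of 20 (adjusted permutation p = 0.007), the nuclear envelope to 9 of 11 (adjusted permutation p = 0.019), transposable elements to 11 of 17 and ribosomal proteins to 37 of 76 (adjusted permutation p = 0.006 each). F-box genes rose to 17 of 31, and defensin-like genes, with 8 of 89, were hit less often than after random placement (adjusted permutation p = 0.019 each). The rRNA genes rose to 4 of 4, all with a replicate 1 peak, but did not pass (adjusted permutation p = 0.09). Random placement does not account for the excess of called H2B peaks in protein-coding genes. The 43 regions with −log10 q of at least 5 in both replicates did not show this excess. Against all other protein-coding genes, about 35.9% of which were hit, photosynthesis and the nuclear envelope also passed (Fisher's exact adjusted p = 0.0472 and 0.0254 over 10 lists), while ribosomal proteins and F-box genes did not (adjusted p = 0.0683 and 0.0760), a comparison chosen after the data were seen that ignores gene length.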

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

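The odds ratios between the fusions were planned before the data were examined, while the tests at the centromeres and rRNA genes, at AT5G46070 and at CRWN4 were chosen only after the regions were seen. GBPL3 and H2B regions differed in the odds of lying in a pericentromere (odds ratio 55.9) and of having a summit in a protein-coding gene (0.0964), in a non-coding RNA gene (11.4, and 0 without the regions near rRNA genes) or in intergenic space (25.2).

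GBPL3 regions gathered beside the centromeres and at the rRNA genes, and DNA that any GFP pulldown brings along, or that piles up at repeats in any library, is a candidate explanation. For the 40 regions within 200 kb of a centromere midpoint, 2.5% (95% interval 0.443 to 12.9) overlapped an H2B peak, against 7.42% after random placement (1-sided permutation p = 0.1897). This argues only against background strong enough to be called in every GFP pulldown. H2B regions were scarce there, with 1 of 815, and the comparison was chosen after the data were seen. Background seen in the GBPL3 libraries alone stays open. For the 11 regions within 10 kb of an rRNA gene, DNA that a GFP pulldown brings along stays open. Of these regions 81.8% (52.3 to 94.9) overlapped an H2B peak, above the 11.5% of random placement (1-sided permutation p = 0.0001, the smallest possible). All these overlaps were with H2B replicate 1, and most of the regions had no peak in replicate 2, the longer list. At all 15 GBPL3 regions with an H2B peak, the median fold was 9.68 for GBPL3 and 1.74 for H2B. Folds of different lists were not tested against each other. A weaker background that shows only where a pulldown brings little other DNA, and is hidden in the H2B libraries, cannot be told apart from binding of GBPL3, since 0 of the peak lists used here come from an input or from a line without a tag. Contact of GBPL3 with chromatin next to the centromeres is the biological hypothesis that also stays open.

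In GBPL3 replicate 2 the highest folds of the list stood beside AT5G46070 (43.8) and in CRWN4 (23.3), genes of a guanylate-binding protein and of a lamin-like protein, and DNA from a construct could account for them. The next stood at AT1G04680 (14.4, ranking 13 of 87 in replicate 1). AT5G46070 and AT1G04680 were the only 2 regions of both replicates with a higher fold in replicate 2. Replicate 2 peaks covered 11.2% of the body of AT5G46070, at the end next to AT5G46060, and 55.1% of CRWN4. Called peaks are not read coverage, and a rise along a whole gene could also lift its local background. Whether it did depends on the control used for peak calling, which is unknown. The covered share therefore cannot decide on DNA of a whole transgene, which stays open at AT5G46070. For CRWN4 the labels name no construct that carries the gene. GBPL3 replicate 1, from the same line, had no peak in CRWN4, so a transgene of the line is not shown there. A short fragment in replicate 2 alone cannot be told apart from binding at AT5G46070, since the replicate 1 peak there (fold 7.13, −log10 q 14.9, ranking 30 of 87 by fold) leaves the height in replicate 2 open. Nor can it at CRWN4, since the peak of 23.3 is in 1 of the 2 GBPL3 libraries, while the H2B lists had a single weak peak in the gene (replicate 2, fold 1.60, −log10 q 1.62). The gene table does not say whether AT5G46070 is the gene carried by the GBPL3 line.

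On the mitochondrial and plastid chromosomes, left out of the comparisons except for an alternative of the GBPL3 replicate overlap (75.6% with them kept), the GBPL3 lists held peaks where the H2B lists held 0. There were 3 mitochondrial peaks in replicate 1 and 2 in replicate 2, with 2 of those in replicate 1 overlapping replicate 2 peaks, and 2 plastid peaks in replicate 2, with folds between 1.63 and 3.92. The 2 shared mitochondrial peaks had folds of 3.92 and 3.73 in replicate 1 and of 2.78 and 2.41 in replicate 2. Both were lower in replicate 2, as were 62 of the 64 nuclear regions. Whether these share a cause was not tested.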

How the results depend on the processing

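Leaving out regions near rRNA genes, joining that or the omission of H2B replicate 1 with placement inside the compartment, setting gene lists against other protein-coding genes, counting loci once, a fold of at least 5 in both replicates and the top H2B regions by fold were chosen after the data were seen; the other alternatives were planned. Of 209 alternative values, 169 kept their direction and their side of the threshold, among them those of the replicate overlaps, the pericentromeric shares and the pericentromeric odds ratio. Over its alternatives the GBPL3 pericentromeric share ranged from 52.9% (loci) to 92.2% (4 Mb), that of H2B from 3.19% (2 Mb) to 15.7% (4 Mb), and the odds ratio from 9.95 (loci) to 129 (2 Mb). The overlap of GBPL3 with H2B fell to 11.3% without the rRNA regions (not passing, but passing against 3.37% inside the compartment), and lay between 6.25 and 23.4% with a library left out, at 6.25% without H2B replicate 1 (below random placement, and above it but not passing inside the compartment). Without the rRNA regions 0% of GBPL3 summits lay in non-coding RNA genes (odds ratio 0), since all 5 such regions were left out, and 1.89% in pseudogenes, and neither passed. With placement inside the compartment the GBPL3 share in protein-coding genes (29.7%) and the H2B share in pseudogenes (4.05%) lay close to random placement (29.8 and 3.98%). By any overlap, 31.3% of GBPL3 regions lay within 1 kb of a gene and no longer passed. By the same measure 2.09% of H2B regions touched a non-coding RNA gene, fewer than random as before but now passing. With a replicate left out the GBPL3 share within 1 kb of a gene ranged from 12.3 to 17.2% (not passing without GBPL3 replicate 2). The H2B share in non-coding RNA genes ranged from 0.743 to 1.32% (below random in each, passing only without H2B replicate 1). With −log10 q of at least 5, 43 H2B regions remained, 34.9% in protein-coding genes (now fewer than random), 16.3% in pseudogenes, 6.98% in non-coding RNA genes and 20.9% in intergenic space (each now more than random), and 20.9% within 1 kb of genes (still fewer); none of these passed. With peaks of either replicate, mostly H2B replicate 2, the H2B hits were 13 in photosynthesis, 9 in the nuclear envelope, 11 in transposable elements (3 by gene body alone, which also passed), 17 in F-box, 37 in ribosomal proteins (from fewer to more than random) and 8 in defensin-like genes (fewer than random). Against other protein-coding genes 13 and 9 passed and 37 and 17 did not. Of the values that passed in neither setting 14 turned direction. Among them were the H2B non-coding share at the stricter q and, set against other protein-coding genes, the 37 ribosomal proteins. In that comparison NLR-type resistance, heat shock, histone H2B and guanylate-binding genes turned too. The others were hits with peaks of either replicate, for H2B 113 in tRNA, 4 in NLR-type resistance, 2 in heat shock and 3 in histone H2B genes (now more than random) and 1 in the guanylate-binding family (now fewer), for GBPL3 1 each in the nuclear envelope and defensin-like genes (now more), and, by gene body alone, 0 for H2B in salicylic acid and immunity (now fewer). The cause of these changes was not tested except where named.

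The replicate numbers pair nothing that the labels name, and 4 regions called in all 4 lists were too few to check for pairing. With the replicate number as a block, over single lists, the pericentromeric odds ratio was 44.2 and that for summits within 1 kb of a gene was 2.57, which then passed; no other odds ratio changed its call. Depth is unknown, and whether it accounts for the longer H2B replicate 2 list was not tested.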

Other observations

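The comparison of strong with weak H2B regions below was chosen after the data were seen. The 43 H2B regions with a −log10 q of at least 5 in both replicates differed from the other 772 in the genes beneath them. Summits in protein-coding genes made up 34.9% of the strong and 84.1% of the other regions (15 of 43 against 649 of 772, odds ratio 0.102, 95% interval 0.0491 to 0.204, Fisher's exact p = 4.46e-12). Pseudogenes made up 16.3% against 3.37%, intergenic space 20.9% against 2.59% and non-coding RNA genes 6.98% against 0.389%. Strong regions in or beside named genes, picked after their values were seen, included NCED3, an abscisic acid synthesis gene (AT3G14440, chromosome 3, 4831436 to 4833748, folds of 2.56 and 2.38), and COL4, a relative of CONSTANS (AT5G24930). The hypothesis that strong and weak H2B calls stand for different kinds of site, the weak ones spread over genes, may be followed up with read counts, since regions are not replicates and the test used the data in which the pattern was seen.

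The peaks of GBPL3 replicate 2 alone included weak ones in GRP7, an RNA-binding protein gene in a chromosome arm (AT2G21660, chromosome 2, 9265382 to 9265708, fold 2.83, −log10 q 1.88), and, in pericentromeric chromatin of chromosome 4, UBQ10, a polyubiquitin gene (AT4G05320, 2718753 to 2719077, fold 3.23, −log10 q 2.98). In replicate 1 alone, LRP1 (AT5G12330, chromosome 5, 3988826 to 3989095) had a fold of 3.27 and a −log10 q of 1.50. The peaks in GRP7 and LRP1 also overlapped an H2B peak, and the peak in UBQ10 did not. These genes were named after their values were seen.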
